A study of Mus musculus with 6 samples.

How the data were processed

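RNA from neuralized embryoid bodies, which are aggregates of mouse embryonic stem cells grown in suspension under conditions that favour neural differentiation, was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array per sample. The stem cell line carried a transgene for FLAG-tagged Gli1, a transcription factor of the hedgehog pathway, under the constitutive Rosa26 promoter, per the labels. After 2 days in suspension the cultures received 500 nM all-trans retinoic acid (RA) for 3 days, with or without 50 nM Ag1.3, an agonist of Smoothened, the membrane protein that carries the hedgehog signal into the cell. Each group had 3 replicates, and the series' design text describes them as parallel cultures paired by number. Total RNA was isolated with a mirVana kit and biotin-labelled cRNA was made with the 3' IVT Express kit, per the labels' protocols. The array reads mainly the 3' end of transcripts, so it does not separate most isoforms.

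The deposited values were probe set intensities on a linear scale, 1 per probe set and array. The summary method, the software and the scaling between arrays are not given in the sources used here. Between 1.68% and 1.75% of the values on each array were exactly 1. Another 1 to 4 values on each array were lower, down to 0.84, so 1 was not a strict limit, and the reason for the equal values is not given in the sources. Medians over all rows of the table ran from 48.79 to 52.71, so the arrays had been brought to a similar overall level or had started there, and an equal shift of most genes would not be visible. Intensities were not scaled to the hybridization spikes, which read 0.19 higher on the log2 scale on Ag1.3 arrays, so fold changes of that size or less depend on the overall level taken as equal. The 18 intensities of 3 control probe sets for Trp genes, with no matching spike, lay between 4.02 and 20.71 with a median of 7.5, and values in that range were read as close to background. No genome build was named for the array values, so no coordinates are given.

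The table held 45101 probe sets, of which 64 were controls and were left out. Of the other 45037, the platform annotation paired 34945 with 1 gene symbol and 932 with several, and 9160 were not listed in it. Among those with 1 symbol, 34741 matched a gene of the RefSeq annotation of GRCm38.p6 by gene identifier, all with an equal symbol. Each of the 18193 genes was represented by its probe set with the highest mean over the 6 arrays, a choice that ignored the treatment. There were 9010 genes with several probe sets. For the named genes that changed, 32 further probe sets existed, of which 30 had the same sign of change and 2 the opposite sign, neither of these with an unadjusted p under 0.05.

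Intensities were transformed to log2(intensity + 16), and fold changes are on that scale, which understates the change of genes of low intensity. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with the replicate number as a block and the treatment as the tested term, and p-values were adjusted by Benjamini-Hochberg over all 18193 genes with a threshold of 0.05. The tests are two-sided. Means ± SD are of deposited intensities with n = 3 per group, and SE is limma's moderated standard error of the log2 fold change. The p-values measure how the change with Ag1.3 varies between 3 pairs of parallel cultures of 1 cell line. The block takes out level differences between pairs, and the number of arrays limits the precision. Deviations from the group mean correlated across genes at 0.54, 0.19 and 0.56 for arrays with the same number, against -0.51 to 0.07 for arrays with different numbers, so the data also paired the arrays. Genes are not independent replicates in these correlations. No array duplicated another, with 21 to 37 equal intensities above 1 between replicates of a group.

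Gene lists were tested with limma's camera, a competitive test that asks whether the members of a list shifted relative to all other genes, with its preset correlation between genes of 0.01 and Benjamini-Hochberg adjustment over 26 lists. Camera with an estimated correlation and fry, which asks whether the members move one way without comparing them with other genes, were run as alternatives. The form with an estimated correlation also judges its statistic by the few degrees of freedom left after the fit of 3 pairs. This costs power whatever the correlation. For the cholesterol synthesis list the estimated correlation was -0.0052, below the preset, and camera's unadjusted p still went from 2.40e-10 to 0.021. The lists, the tests, the block, the alternatives and the rule for naming genes were fixed before the data were examined. The rule took the 10 genes with the largest increase and the 10 with the largest decrease among those past the threshold with the same direction in all 3 pairs. It added from each list up to 3 members with the smallest adjusted p past the threshold, or the 2 with the smallest p where none passed. A fixed set of hedgehog pathway and neural tube patterning genes was named whatever their values. Some list members were not analysed here and are not reported.

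The gene test was tested on simulated data with 18193 genes, variances drawn from the fitted prior and 200 changed genes in each of 5 draws. It recovered 10.4% of genes changed by 0.5 on the log2 scale, 87.6% at 1, 99.2% at 2 and 100% at 3, and 4.25% of its calls were false. The simulated residuals were normal, independent between genes and unrelated to intensity, so the assumptions of the test held by construction. The share of false calls in the real data can differ. Camera called 20 of 20 simulated lists of 15 genes shifted by 0.7 and 0 of 180 unshifted ones, without correlation between genes. Alternatives covered the block, the moderation of variances, a filter on dim probe sets, the choice of probe set, 2 normalizations between arrays, array weights, the pseudocount, a test against a fold of 1.5, the set test and each pair left out in turn. The alternative moderation, called below the moderation that follows intensity, used an intensity trend and robust estimation together. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.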

Results

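Gene expression was measured in 6 cultures of embryoid bodies made from mouse embryonic stem cells that carried the Gli1-FLAG transgene. The 3 RA cultures received retinoic acid, which directs such aggregates towards neural fates of hindbrain and spinal cord level. The 3 Ag1.3 cultures received retinoic acid and the Smoothened agonist. Each RA culture had an Ag1.3 culture grown in parallel, which makes 3 pairs. Median intensities without control probe sets were 48.68, 51.89 and 50.44 in RA replicates 1 to 3 and 48.76, 49.87 and 52.55 in Ag1.3 replicates 1 to 3. Replicates of a group correlated across genes at 0.982 to 0.992 on the log2 scale, where genes are not independent replicates. Actin 3' to 5' signal ratios, a measure of RNA integrity, were 1.46 to 1.51 in RA and 1.33 to 1.63 in Ag1.3 arrays, and Gapdh ratios were 0.903 to 0.932 and 0.932 to 0.962. Hybridization spikes averaged 9.38 to 9.67 on the log2 scale on RA arrays and were higher on all Ag1.3 arrays, at 9.70 to 9.78, a shift of 0.19. The first principal component of the 2000 most variable genes held 57.0% of their variance and the second 28.9%, and pair 3 lay apart from pairs 1 and 2.

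The comparison asks which genes of whole embryoid bodies differ after 3 days of stimulation of the hedgehog pathway. It does not separate a response within cells from a change in the mix of cell types. With Ag1.3, 6 of 13 floor plate genes, 6 of 8 genes of ventral progenitors and V3 neurons and 8 of 16 motor neuron genes rose, and 7 of 16 genes of dorsal and intermediate progenitors fell. These 4 lists passed camera's test at its preset correlation and did not pass with an estimated correlation, where adjusted p was 0.206 to 0.288. The second form has few degrees of freedom with 3 pairs, so a miss there says little about any list. Olig2, a transcription factor of motor neuron progenitors, had the largest increase and went from 16.7 ± 8.08 to 830 ± 360 (SD, n = 3 each). Pax7, a transcription factor of dorsal progenitors, went from 266 ± 175 to 6.69 ± 2.57, a background value, and passed in 5 of 14 alternatives. With Pax3 and Dbx1 it had the largest decreases, at -3.34, -3.32 and -3.29 on the log2 scale, and Dbx1 was first of these at a pseudocount of 64, with the mean of probe sets, and without pair 1 or 2. In limma's test 252 of 18193 genes changed, 195 of them higher and 57 lower with Ag1.3, and all 252 had the same direction in all 3 pairs. At least 2-fold changes were found for 108 of them, 87 higher and 21 lower. The share of higher genes, 77.4%, rests on the setting, since the test without the replicate block called 86 genes and a moderation that follows intensity called 1210, of which 52.9% were higher. Without pair 1, 2 or 3 the count was 39, 35 or 62.

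**Figure D1:**
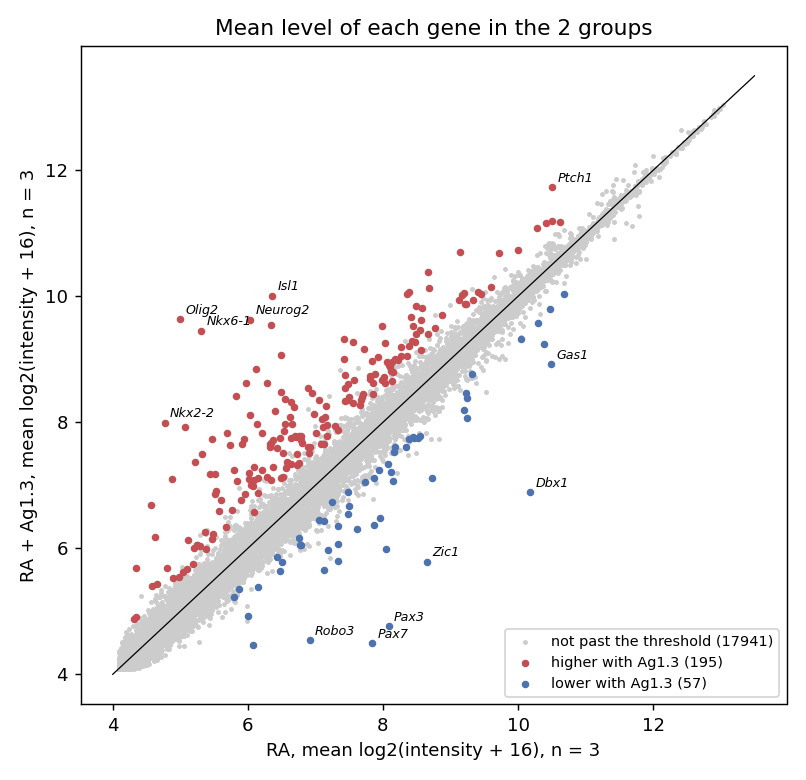
Mean log2(intensity + 16) of each of the 18193 genes in the RA cultures (horizontal axis) and the Ag1.3 cultures (vertical axis), n = 3 each, with the line of equal values. Red points are the 195 genes higher and blue points the 57 genes lower with Ag1.3, and Olig2 and Pax7 lie far from the line on opposite sides.

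Among the 10 largest increases were transcription factors of ventral progenitors and of motor neurons. Nkx6-1 rose from 25.7 ± 15.3 to 697 ± 156 and Nkx2-2, a marker of the most ventral neuronal progenitors, from 11.4 ± 3.23 to 245 ± 69.2. Isl1, which is needed for motor neuron formation, rose from 66.9 ± 11.3 to 1031 ± 230, and Lhx3, its partner in motor neurons, from 17.5 ± 1.81 to 250 ± 130, while its other probe set went from 30.3 to 60.7, a log2 fold change of 0.69 against 2.86. Neurog2, a proneural factor, rose 12.1-fold, Olig1 9.26-fold, Spon1, an extracellular protein of the floor plate, 6.65-fold, and Nkx2-9 6.26-fold. Clstn2, a synaptic adhesion protein, rose 6.06-fold. Among the 10 largest decreases, Pax3 fell from 299 ± 189 to 11.3 ± 4.17 and Dbx1, a factor of intermediate progenitors, from 1199 ± 419 to 134 ± 98.1. Zic1, a dorsal factor, was 7.30-fold lower. The chosen probe set of Robo3, a receptor of commissural axons, fell from 112 ± 48.7 to 7.41 ± 2.96, and its other probe set did not fall (33.6 to 35.3, log2 fold change 0.05, unadjusted p = 0.53). The long noncoding RNA Rmst was 4.14-fold lower, Uncx fell from 55.9 ± 32.1 to 6.19 ± 2.22, and Gm3515 was 3.05-fold lower, Gas1 2.97-fold and Frzb, a secreted Wnt antagonist, 2.92-fold lower. Dimmer probe sets gave smaller decreases on the log2 scale for Pax7 (-1.92), Zic1 (-1.69), Frzb (-0.82) and Rmst (-0.51). Of the further Pax3 probe sets, 1 gave -2.14 and the other -3.35. Adjusted p ranged from 0.00287 for Olig1, Spon1 and Clstn2 to 0.0492 for Frzb. Of 14 alternatives Frzb passed in 6, Gm3515 in 7 and Zic1 in 8, Uncx passed in 8 of 13, and the genes other than these and Pax7 passed in 10 to 13. Without pair 1, 2 or 3, 8, 7 or 8 of the 10 increases and 2, 2 or 8 of the 10 decreases passed, and 10 and 4 without the replicate block. With a pseudocount of 1, 0 of either 10 passed in limma's test, all of them with an unadjusted p under 0.05. The chosen probe sets of Pax7, Pax3, Robo3 and Uncx with Ag1.3, and of Olig2, Nkx2-2 and Lhx3 in RA, had means in the range of the unspiked control probe sets, so their folds depend on the pseudocount.

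Feedback targets of the hedgehog pathway are genes that the pathway switches on in its own responding cells, and 2 of 5 rose with Ag1.3. Ptch1, the receptor for the hedgehog ligand and a direct target of the pathway, rose from 1482 ± 473 to 3424 ± 596, a log2 fold change of 1.23 with SE 0.13 and adjusted p = 0.0235. Rab34 rose from 586 ± 56.6 to 936 ± 166. Gli1 read 139 ± 62.8 in RA and 331 ± 71.2 with Ag1.3, higher in 3 of 3 pairs, and did not pass the threshold with a log2 fold change of 1.21, SE 0.22 and adjusted p = 0.0791. Whether the single Gli1 probe set also reads the transgene is not given in the sources, so its signal cannot be assigned to the endogenous transcript alone. Hhip, a membrane protein that binds hedgehog ligand, had a log2 fold change of 0.59 and adjusted p = 0.0927. Its other 3 probe sets, all dimmer, gave 0.87, 1.06 and 1.3, with unadjusted p of 0.00088, 0.0010 and 3.8e-05. Adjusted over the list alone, 4 of the 5 rose. Camera placed the list above other genes with adjusted p = 6.78e-06, and adjusted p = 0.206 with an estimated correlation. Without the replicate block, and without any 1 of the pairs, 0 of the 5 passed in limma's test and 4 had an unadjusted p under 0.05.

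Among receptors and transducers of the pathway, 2 of 16 fell. Gas1, a membrane protein that helps cells bind hedgehog ligand, fell from 1466 ± 413 to 477 ± 104, and Gli3, which acts mainly as a repressor of hedgehog targets, from 603 ± 157 to 255 ± 42.1. Adjusted over the list alone 3 fell, Cdon being the additional one. Gli2 had a log2 fold change of -0.08 with adjusted p = 0.706 and did not pass. The list shifted down with adjusted p = 0.00057, and adjusted p = 0.288 with an estimated correlation. Of the further Gli3 probe sets, 1 gave -1.16 and the other -0.15 on the log2 scale. Without pair 1, 2 or 3, 1, 1 or 3 of the 16 members passed, Gas1 each time, and neither Gas1 nor Gli3 passed without the replicate block.

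Of floor plate genes, expressed at the ventral midline of the neural tube, 6 of 13 rose. Foxa2, the transcription factor that specifies this structure, went from 66.6 ± 36.6 to 406 ± 180, and Shh, the ligand it secretes, from 86.9 ± 3.41 to 301 ± 113. Slit3, an axon guidance ligand, rose 3.73-fold. Adjusted over the list alone, 7 members rose. The list shifted up with adjusted p = 8.45e-09, and adjusted p = 0.206 with an estimated correlation. Progenitor genes of the ventral domains and of V3 interneurons rose as well, with 6 of 8 members past the threshold and 7 adjusted over the list alone. Nkx6-2 rose from 4.40 ± 2.92 to 36.1 ± 9.16, the first value being close to background, and Sim1, a V3 neuron gene, was not past the threshold. This list had a median log2 fold change of 2.93 and adjusted p = 5.33e-11, and adjusted p = 0.206 with an estimated correlation. RA replicate 3 differed from the other RA arrays in these genes, with 15 of 17 floor plate and ventral genes above the mean of these 2 arrays and a median deviation of 0.41 from it. These 17 were those of the 21 measured with a mean above the median probe set. That mean was taken over all 6 arrays, so some of the 17 were near background in RA. In RA replicates 1 to 3 Olig2 read 17.0, 8.51 and 24.7 and Nkx2-2 7.88, 14.2 and 12.1. Without pair 1, 2 or 3, 4, 6 or 3 of 13 floor plate and 5, 4 or 3 of 8 ventral members passed, and 3 and 6 without the replicate block.

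Genes of dorsal and intermediate progenitor domains fell, with 7 of 16 past the threshold and 10 adjusted over the list alone. Besides Pax7, Pax3, Dbx1 and Zic1, these were Irx3, which went from 1428 ± 635 to 659 ± 326, and Irx5 and Zic5. Pax6, which is graded along the neural tube, read 615 ± 236 and 435 ± 168, a log2 fold change of -0.48 with adjusted p = 0.0535. Dbx2 was close to background in both groups, with a log2 fold change of 0.04. The list shifted down with adjusted p = 2.35e-08, and adjusted p = 0.206 with an estimated correlation. Roof plate and dorsal midline genes shifted down with 0 of 13 past limma's threshold over all genes, 5 at an unadjusted p under 0.05 and 4 adjusted over the list alone, among them Rspo1 at -0.42 and Msx3 at -0.49 on the log2 scale. Their adjusted p was 0.00601, and adjusted p = 0.288 with an estimated correlation. Without the replicate block 3 had an unadjusted p under 0.05, and 2 fell under the moderation that follows intensity. RA replicate 3 read below the mean of the other RA arrays in 7 of 9 dorsal and intermediate genes, with a median deviation of -1.09. These 9 were those of the 16 with a mean above the median probe set. Without pair 1, 2 or 3, 1, 1 or 4 of the 16 members passed, 2 passed without the replicate block, and Pax7 passed in 5 of 14 alternatives.

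**Figure D2:**
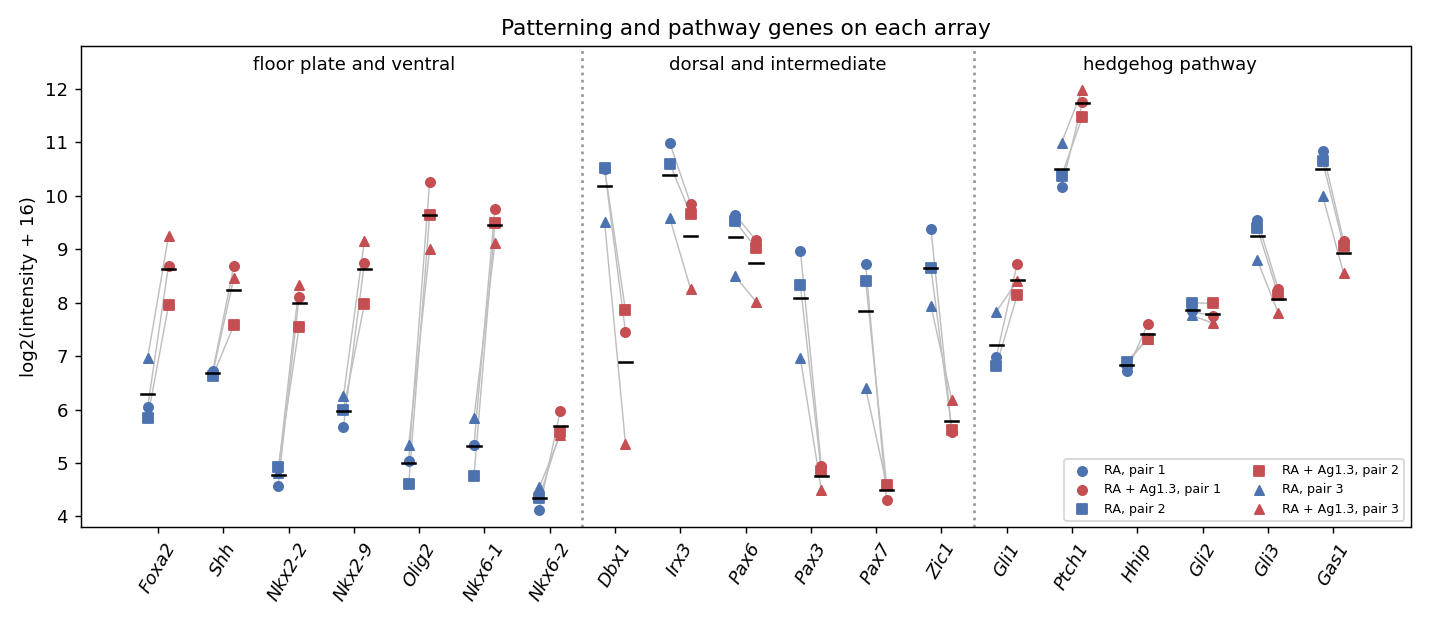
Log2(intensity + 16) of 19 patterning and hedgehog pathway genes on each of the 6 arrays, RA in blue and RA with Ag1.3 in red, with a marker shape for each pair, grey lines joining the arrays of a pair and black bars for group means (n = 3). Olig2, Nkx6-1 and Nkx2-2 are higher and Pax3, Pax7 and Dbx1 lower with Ag1.3 in all 3 pairs.

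Motor neuron genes rose, with 8 of 16 past the threshold and 9 adjusted over the list alone. Phox2a, a factor of cranial motor neurons, went from 21.1 ± 1.64 to 150 ± 22.6, and Slc18a3, the vesicular acetylcholine transporter, rose to 124 ± 38.1 from a mean in the range of the unspiked controls, with a log2 fold change between 1.26 and 3.12 over the alternatives. The motor neuron list shifted up with adjusted p = 7.45e-11, and adjusted p = 0.288 with an estimated correlation. Of the 16, 3, 2 or 5 passed without pair 1, 2 or 3, and 6 without the replicate block. Genes shared by most neurons rose too, with 16 of 22 past the threshold, 21 adjusted over the list alone and a median log2 fold change of 1.14. Neurod4, a neurogenic transcription factor, rose 5.95-fold from 74.7 ± 10.1 to 533 ± 142. Elavl4, an RNA-binding protein of neurons, rose 3.24-fold, and Stmn2, which regulates microtubules in growing axons, 2.93-fold. Syt1 was the 1 member with a value below 0, at -0.11. The general neuron list had the smallest adjusted p of all, 4.80e-30, and adjusted p = 0.206 with an estimated correlation. Of its 22 members 6, 5 or 8 passed without pair 1, 2 or 3, and 8 without the replicate block.

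Not all neuronal genes rose. In the list of interneurons of dorsal and intermediate origin, Lhx1 went from 195 ± 91.9 to 66.3 ± 26.7 and Lhx5 fell from 50.2 ± 19.6 to a mean in the range of the unspiked controls. These 2 of 18 fell, 3 adjusted over the list alone, and the list as a whole did not pass with adjusted p = 0.321. Neither gene passed without pair 1, without pair 2 or without the replicate block. General neural progenitor genes shifted up by a median of 0.18, with Notch1, which rose from 594 ± 155 to 942 ± 220, the 1 of 15 past the threshold. Adjusted over the list alone 3 rose and 1 fell. Their adjusted p was 0.00182, and adjusted p = 0.398 with an estimated correlation. Without the replicate block this list did not pass, with adjusted p = 0.128. Notch1 did not pass there, nor without any 1 of the pairs. Sox2, a factor of neural progenitors and pluripotent cells, read 2769 ± 113 and 2586 ± 109, with adjusted p = 0.624.

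In the Notch list, Mfng, a glycosyltransferase that modifies Notch receptors, rose from 110 ± 28.8 to 358 ± 142, Hey2, a repressor downstream of Notch, from 54.4 ± 9.88 to 237 ± 35.3, and the ligand Dll3 1.90-fold. With Hey1, 4 of 14 members rose, and 6 adjusted over the list alone. The list shifted up with adjusted p = 0.000178, and adjusted p = 0.206 with an estimated correlation. Of the 14, 1, 2 or 1 passed without pair 1, 2 or 3, and 2 without the replicate block. Genes of cholesterol synthesis read higher together by small amounts. Dhcr7, the last enzyme of the pathway, had a log2 fold change of 0.49 (adjusted p = 0.0586) and Insig1, its feedback regulator, 0.40 (adjusted p = 0.0808). In limma's test 0 of 15 members passed over all genes, and 11 had an unadjusted p under 0.05 and also passed adjusted over the list alone. Without the block 4, and without pair 1, 2 or 3, 7, 7 or 11 had an unadjusted p under 0.05, while 11 passed over all genes under the moderation that follows intensity. All 15 values were above 0. The list shifted up with adjusted p = 1.25e-09, and adjusted p = 0.206 with an estimated correlation.

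Genes of pluripotent cells read lower. Pou5f1, which maintains pluripotency, fell from 348 ± 126 to 215 ± 97.6 and was the 1 of 13 past the threshold, with 10 adjusted over the list alone. Under the moderation that follows intensity 10 of the 13 passed, and without the replicate block 0 passed in limma's test, with 0 at an unadjusted p under 0.05. All 13 values were below 0, with a median of -0.58. The list shifted down with adjusted p = 1.20e-09, and adjusted p = 0.206 with an estimated correlation. In the endoderm list Sox17, an endoderm transcription factor, fell from 138 ± 67.3 to 52.0 ± 35.7 (log2 fold change -1.21, and -0.47 by its other probe set) and Krt8, a keratin of simple epithelia, 1.54-fold. These were 2 of 16, with 5 adjusted over the list alone. The liver and yolk sac genes Afp, Ttr and Apoa1 had log2 fold changes of -0.03, 0.03 and -0.03. The endoderm list shifted down with adjusted p = 0.0112, and adjusted p = 0.378 with an estimated correlation, and it did not pass without the replicate block (adjusted p = 0.133). Of immediate early and heat shock genes, Hspb1, a small heat shock protein, fell from 1491 ± 637 to 937 ± 426 and Ier3 1.43-fold, which were 2 of 14 both over all genes and adjusted over the list alone. That list shifted down with adjusted p = 0.00502, and adjusted p = 0.366 with an estimated correlation. Among genes above the median probe set it did not pass (adjusted p = 0.222). None of Pou5f1, Sox17, Krt8, Hspb1 and Ier3 passed without the replicate block or without any 1 of the pairs.

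Among the lists without a shift, some members changed. Hoxb5 rose from 1056 ± 348 to 1728 ± 416, the 1 of 19 Hox genes past the threshold, with 3 higher and 1 lower adjusted over the list alone and adjusted p = 0.313 for the list. En2, a midbrain and hindbrain gene, fell from 150 ± 42.3 to 51.5 ± 11.5, the 1 of 14 in the forebrain and midbrain list, with 2 adjusted over the list alone and adjusted p = 0.943 for the list. Among genes above the median probe set En2 was the 1 member left in that list, at -1.28 on the log2 scale. In the BMP list Hey1 rose from 118 ± 24.7 to 313 ± 35.9 and Id3, a target of BMP signals, fell from 1043 ± 43.8 to 625 ± 6.28. Adjusted over the list alone 2 of its 12 members rose and 4 fell, and the list had adjusted p = 0.204. When each pair was left out in turn, Hoxb5 and Id3 never passed, En2 passed only without pair 1 and Hey1 only without pair 2. Without the replicate block Hey1 and Id3 passed and Hoxb5 and En2 did not.

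In 8 of the lists without a shift, 0 members passed limma's threshold over all genes. Retinoic acid response genes had adjusted p = 0.342 as a list, with Dhrs3 at -0.96 and Cyp26a1, which degrades retinoic acid, at -0.52 on the log2 scale. Of the 15, 5 had an unadjusted p under 0.05, and 1 was higher and 2 lower adjusted over the list alone. Cell cycle genes had adjusted p = 0.174, with Ccnd2 at 0.37 and Mcm5 at -0.18. Of 6 further Ccnd2 probe sets, 5 gave 0.44 to 0.78, with limma's unadjusted p from 0.0015 to 0.0049, and 1 gave 0.28. Of the 21 members, 1 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone. Neural crest genes had adjusted p = 0.102, with Erbb3 at -0.58 and Snai2 at -0.48 as the 2 of 11 with an unadjusted p under 0.05, both lower adjusted over the list alone. Wnt response genes had adjusted p = 0.684, with 3 of 12 at an unadjusted p under 0.05, of which Cdx1 at -0.51 and Lef1 at 0.41 (0.13 by its other probe set) passed adjusted over the list alone. Mesoderm genes had adjusted p = 0.313, with Tbx18 at -0.45 and Tbx6 at -0.25 and 4 of 17 at an unadjusted p under 0.05. Endothelial and blood genes had adjusted p = 0.684, with Kdr at 0.57 and Pecam1 at -0.37 and 3 of 13 at an unadjusted p under 0.05. Hypoxia genes had adjusted p = 0.0992, with Vegfa at 0.41 (0.04 by its other probe set) and Bnip3 at 0.46 and 4 of 17 at an unadjusted p under 0.05. Genes of the integrated and endoplasmic reticulum stress responses had adjusted p = 0.607, with Atf3 at -0.42 and Asns at -0.22 and 3 of 14 at an unadjusted p under 0.05. In these last 4 lists 0 members passed adjusted over the list alone. Over the 8 lists, 0 to 4 members of each passed under the moderation that follows intensity, and 0 to 3 had an unadjusted p under 0.05 without the replicate block. The hypoxia list passed without the replicate block (adjusted p = 0.0444) and without pair 2 (adjusted p = 0.00976).

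**Figure D3:**
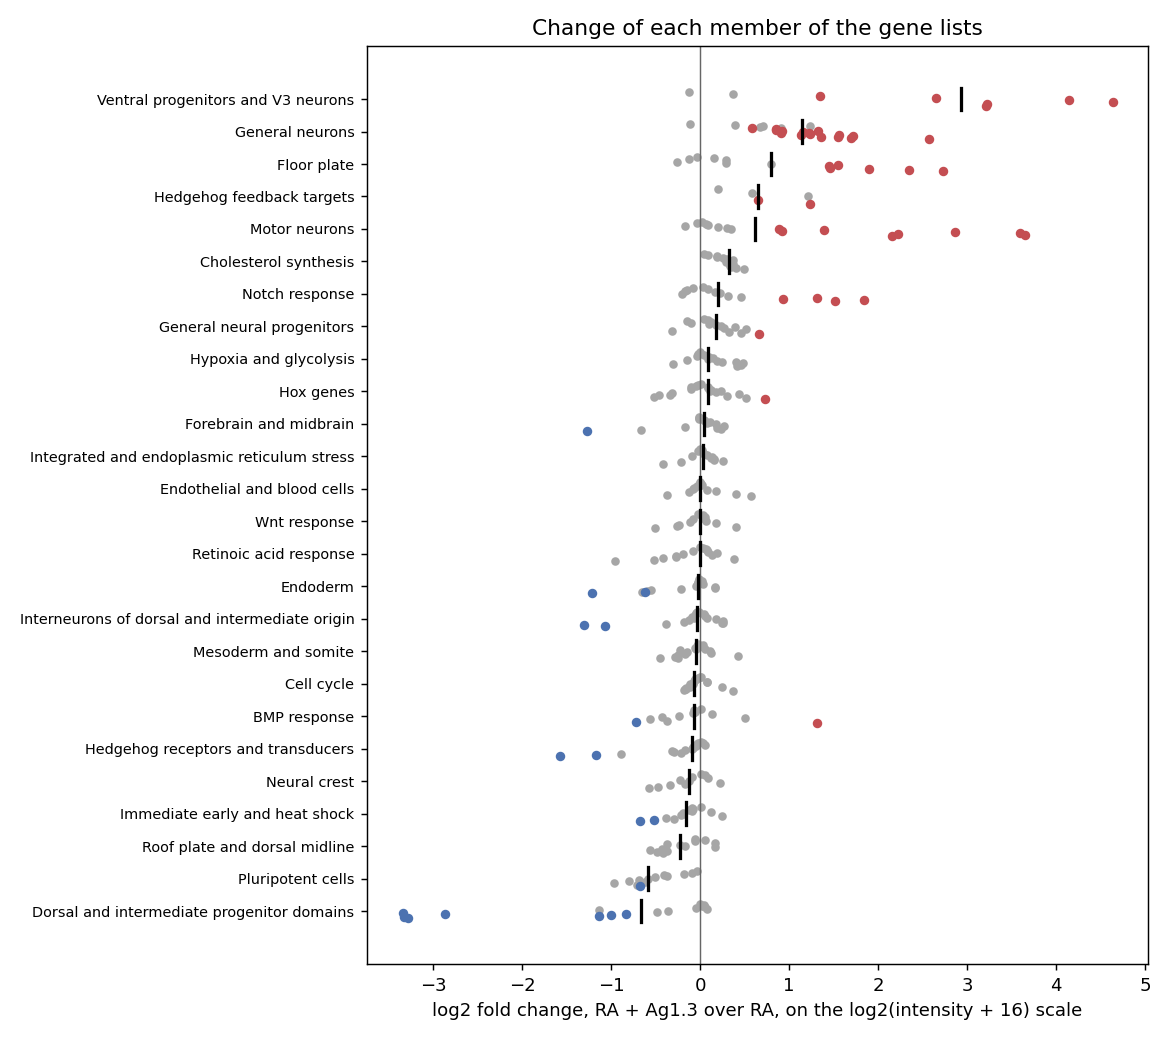
Log2 fold change of each measured member of the 26 gene lists, RA with Ag1.3 over RA, on the log2(intensity + 16) scale, with a black bar at each list's median. Red and blue points are members past the threshold over all genes, higher and lower with Ag1.3, grey points are the others, and the median of the ventral list lies at 2.93.

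Of the 26 lists, 14 passed camera's test, 8 shifted up and 6 down. With an estimated correlation 0 passed, with 3 at an unadjusted p under 0.05, while fry called 9, 7 up and 2 down. The medians and the tests of all 14 had the same sign. In the forebrain and midbrain list and in the Wnt list, neither of which passed, the median was above 0 (0.05 and 0.00016) and the mean below it (-0.07 and -0.04).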

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

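The tests of the array quality of RA replicate 3 and of its hedgehog targets were chosen only after its values had been seen, and the counts over other splits of the arrays were planned. Probe sets that the annotation assigns to no single gene stayed outside the comparison of genes, and 17 of these 10092 changed with Ag1.3, all 17 higher. They were tested together with all other probe sets, 45037 in all, of which 232 changed. Of the 17, 13 were not listed in the annotation and 4 were listed with several genes, and the largest log2 fold change among them was 3.60. No gene is named for them and no explanation was tested.

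RA replicate 3 stood apart from RA replicates 1 and 2, with floor plate and ventral genes higher by a median of 0.41 and dorsal and intermediate genes at a median deviation of -1.09, taken over the 17 of 21 and 9 of 16 genes with a mean above the median probe set. Some of these ventral genes, such as Olig2 and Nkx2-2, were near background in RA. Ag1.3 replicate 3 stood about as far from Ag1.3 replicates 1 and 2, so pair 3 as a whole lay apart. Replicate 3 differed from replicates 1 and 2 with SDs of 0.34 and 0.28 (RA) and 0.34 and 0.29 (Ag1.3) across genes. Replicates 1 and 2 differed from each other with SDs of 0.23 (RA) and 0.24 (Ag1.3) on the log2 scale. A fault of the RA replicate 3 array alone would leave its partner unmoved, and the correlation of 0.56 between the deviations of both arrays of pair 3 argues against it. A uniformly lower intensity would move both gene groups alike, and they moved in opposite directions. Several ventral genes were dim in RA (means of 16.7 for Olig2 and 11.4 for Nkx2-2) and several dorsal and intermediate genes bright (1199 for Dbx1 and 1428 for Irx3). The directions therefore do not exclude a loss of contrast on the array. A technical effect shared by both arrays of pair 3 would also give correlated deviations, and it was not tested. Higher hedgehog activity in that culture without the agonist stays open as a hypothesis, since 2 of 4 feedback targets read higher than on both other RA arrays, Ptch1 at 2018 against 1123 and 1304 and Gli1 at 211 against 110 and 96.4. Rab34 lay below the higher of the other RA arrays by 0.27, more than its residual SD of 0.10, and Hhip, at 101 against 89.1 and 103, by 0.02, within its residual SD of 0.14, and by the bound first written, 2 or fewer of 4, the hypothesis would have been set aside; allowance for the residual SD was added after this count had been seen. Higher activity in that culture alone would not account for deviations that its Ag1.3 partner shared. That sharing was measured over all genes, and ventral and floor plate genes were mixed. Olig2 and Nkx6-1 were highest of the RA arrays on replicate 3 but lowest of the Ag1.3 arrays there (499 and 536). Foxa2 and Nkx2-9 were highest on replicate 3 in both groups (591 and 554 with Ag1.3). The correlation therefore does not decide the hypothesis for these genes. General neuron genes (median deviation -0.56), neural progenitor genes (-0.64) and pluripotent genes (0.49) also deviated on the array of RA replicate 3. A slower neural differentiation of that culture, or of both cultures of pair 3, may contribute and was not tested apart.

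The count of 252 genes, the count of 108 genes changed at least 2-fold and the 14 shifted lists were set against the other splits of the 6 arrays into 3 and 3. There are 10 splits, too few for a share under 0.05, and 1 of the 10, the real one, gave counts as large for each of these results. The other 3 splits that part all 3 pairs, each with the treatment reversed in 1 pair, gave 0 genes, 0 genes changed at least 2-fold and 0 to 4 lists. In these splits a steady treatment effect enters the spread between pairs. Genes that respond alike in all pairs could then hardly pass, so these gene counts are not values without treatment either. The other 6 splits part 1 pair, and with the block their tested term is that pair's own difference between Ag1.3 and RA, so they are not values without treatment. They gave 0 genes, 0 genes changed at least 2-fold and 7 to 11 lists, and 11 was the highest count of lists in any other split.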

How the results depend on the processing

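All alternatives given here were planned, and no test in this part was chosen after a result was seen. Against 252 genes changed and 108 changed at least 2-fold, the fit with no replicate block, which treats the paired arrays as independent, called 86 and 67, and 85 of these 86 were among the 252. Moderation with an intensity trend and robust estimation together called 1210 genes, the filter on dim probe sets 951 and array weights 507. Of these, 52.9%, 52.3% and 58.6% were higher against 77.4%, and these settings held 249, 222 and 252 of the 252 genes. A pseudocount of 64 called 831 and 68 genes, with 56.9% of the 831 higher, and a pseudocount of 1 called 0 and 0 in limma's test, with 2411 genes at an unadjusted p under 0.05. The test against a fold of 1.5 called 29 genes, and all 29 were among the 108. Leaving out 1 pair gave 35 to 62 genes and 35 to 62 changed at least 2-fold, where only 2 pairs are left to estimate the spread; the low counts came without pair 2 (35) and pair 1 (39). The cause was not tested for the other settings. Quantile normalization, median centring and the choices of probe set gave 168 to 357 genes, within 1.5 times of 252, with 69.5% to 80.4% higher. Of the lists, 13 to 15 passed under each alternative that kept camera's preset correlation, 0 with an estimated correlation, where 3 had an unadjusted p under 0.05, and 9 with fry. Among the genes named by the fixed rule Dbx2 alone changed sign, from 0.04 to -0.23 without pair 1, -0.098 without pair 2 and -0.030 with a pseudocount of 1 (0.45 without pair 3), and it passed no test. Other genes named by that rule kept their direction in all alternatives run, and without the block 24 of them no longer passed. Dim genes are limited by the background of 4.02 to 20.71. A change of 0.5 on the log2 scale was recovered in 10.4% of simulated genes, whose variance did not depend on intensity.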

Other observations

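The tests on neuron genes and the use of fry on pluripotent genes, in place of a sign-flip test that 3 pairs cannot bring under 0.25, were chosen only after the results had been seen, as were the genes named in the next paragraph, and the test on further stem cell genes was written before their values were seen.

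Of 6 Iroquois genes, transcription factors of the intermediate and dorsal neural tube, 4 fell with Ag1.3. Irx1 went from 296 ± 150 to 124 ± 43.1, Irx2 from 248 ± 104 to 73.8 ± 6.99 and Irx5 from 626 ± 299 to 308 ± 153 (SD, n = 3), and Irx3 fell as given among the dorsal genes. Irx4 (-0.04) and Irx6 (-0.08) did not pass on the log2 scale, and all 6 signs held under quantile normalization and median centring. Over all alternatives Irx4 kept its sign in 12 of 13 and Irx6 in 13 of 14. Sema3d, a guidance ligand, rose from 24.0 ± 2.57 to 168 ± 43.7, Cntn2, an axonal adhesion protein, from 162 ± 53.8 to 634 ± 127, and Ret, a receptor for GDNF family ligands, from 76.9 ± 28.2 to 345 ± 59.8. Ddc, an enzyme of serotonin and dopamine synthesis, rose from 178 ± 58.1 to 607 ± 86.0. Lefty1 and Lefty2, inhibitors of Nodal signals, fell by 0.90 and 0.72 on the log2 scale, and Fst, which binds activin, fell by 1.46. Ntrk2, a neurotrophin receptor, fell from 222 ± 48.4 to 67.6 ± 14.9. Each gene said here to rise or fall kept its direction under each of 14 alternatives, but passed limma's test in only 8 (Irx1, Lefty2) to 13 (Cntn2) of them. With a pseudocount of 1 these genes did not pass. The Iroquois genes, Lefty1, Lefty2 and Fst did not pass without the replicate block, and Cntn2 alone passed without each of the pairs. Irx1, Irx3, Irx5, Lefty1, Lefty2 and Ret did not pass without any 1 of the pairs. Sema3d did not pass without pair 2 or 3, Irx2, Ddc and Fst without pair 1 or 2, and Ntrk2 without pair 2.

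Families of genes that share a symbol root were also compared by camera, 310 families of at least 8 genes. The Nkx family alone passed, with 12 genes, 4 of them higher past the threshold and adjusted p = 0.0128, and adjusted p = 0.994 with an estimated correlation. The protocadherin beta family had 17 of 22 genes above 0, 0 past limma's threshold and camera's adjusted p = 0.0543, and adjusted p = 0.994 with an estimated correlation.

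A probe set of Naca read 17932 on Ag1.3 replicate 3 and 3023 to 3283 on the other 5 arrays. Naca's chosen probe set is another one, and its log2 fold change was 0.0027.

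General neuron genes had a median log2 fold change of 1.14 with Ag1.3. More neurons of every kind would raise interneuron genes of dorsal and intermediate origin too, but the median of the 5 such genes above the median probe set was -0.031, with an SD of 0.59 over these few genes. Genes of dorsal and intermediate progenitors fell as well, so fewer such interneurons could form whatever the rate of neuron formation. The interneuron genes therefore do not decide whether neuron formation rose in general. Fewer pluripotent cells would raise alike the neuron genes and those progenitor genes that pluripotent cells lack, but progenitor genes had a median of 0.18 with an SD of 0.26. That list also holds Sox2, a factor of pluripotent cells too, so it is not a clean measure of this. A gain of ventral neurons, with motor neurons among them, or earlier differentiation of ventral progenitors may underlie the rise, and the data do not separate these.

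Pluripotent genes had a median log2 fold change of -0.58. Fewer undifferentiated cells with Ag1.3 would lower other stem cell genes as well, and 10 of 10 further such genes, for example Dppa4 (684 to 421) and Fbxo15 (682 to 454), had values below 0 with a median of -0.58, although in limma's test 0 of them passed the threshold over all genes. The list's mean changes of -0.59, -0.60 and -0.35 in the 3 pairs had a mean of -0.51 and an SD of 0.14, and fry, which sets such changes against the spread between pairs, gave adjusted p = 0.0463. This argues against variation between parallel cultures as the whole cause, but weakly, since fry was chosen after its result had been seen and its value lies near the threshold. Camera with an estimated correlation, which has few degrees of freedom here, gave adjusted p = 0.206. A smaller share of undifferentiated cells may underlie the change, and a direct effect of the agonist on these genes was not tested.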
